A study of Mus musculus with 12 samples.

How the data were processed

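Liver RNA was measured on 12 single-colour microarrays, 3 for each of 4 groups. Per the labels, 24 male C57BL/6 mice were kept, 6 in each group, and liver was taken after an overnight fast. The normal diet (ND) held 12.3% fat, 21.5% protein and 66.2% carbohydrate. The high-fat diet (HFD) held 36.1% fat, 21.6% protein and 42.3% carbohydrate, with lard, egg yolk powder, bile salt and 2% cholesterol added. The groups were ND for 24 weeks, HFD for 16 weeks (HFD16), HFD for 24 weeks (HFD24), and HFD with PTFC, the flavonoid extract of citrus under study, given into the stomach at 50 mg per kg per day over 18 weeks after 6 weeks of HFD alone (PTFC). The other groups received saline. Mice of the HFD16 group were 23 to 25 weeks old at collection and those of the other groups 30 to 33 weeks, so age differs wherever HFD16 is compared. Collection day, for which no date was used here, may differ there too. The titles give each array its own code, and the first ND replicate has another age range than the other ND replicates. The labels number the replicates 1 to 3 in each group without saying that each came from a separate animal. The p-values therefore measure only the spread between these samples, which may be technical. What the labels say of the light cycle contradicts itself and was not used.

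Per the labels' protocols, total RNA was extracted with Trizol, amplified with amino-allyl nucleotides and labelled with Cy5. The deposited values are linear intensity values of 26423 probes on each array. How the authors subtracted background, scaled the arrays, averaged spots and chose probes is not given in the sources used here. Of the 317076 intensity values the authors deposited, 291 were below 0 and 133 were 0, together 0.134%. On every array at least 99.98% of the values were whole multiples, within a tolerance of 0.02, of a step between 0.675 and 1.46 that belonged to that array, as one scaling factor per array would leave. The mean step was 1.31 ± 0.133 (SD, n = 3) for ND, 0.921 ± 0.213 for HFD16, 0.976 ± 0.137 for HFD24 and 0.947 ± 0.0872 for PTFC. Array medians lay between 249 and 408 and the quantiles of the arrays did not coincide. No detection flag, slide number or scan date was used here. For arrays, the number per group limits the precision.

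The platform table paired 21876 probes with 1 gene symbol, no probe with several, and left 4547 unnamed here. Of the named probes, 21825 carried a symbol found in the RefSeq gene table. The named probes stood for 19084 genes, 2424 of them with more than 1 probe, and the probe with the highest mean over the 12 arrays was kept for each gene. Values below 0 were set to 0, which touched 162 probes, and log2 of the intensity plus a pseudocount of 1 was quantile normalized over the 12 arrays. A difference is therefore on the log2(intensity + 1) scale and understates the change of dim genes. The dimmest 25% of genes had a mean log2 intensity under 6.84. No genomic coordinates were used.

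Group means were fitted to all 12 arrays with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with a trend in the prior variance), without a replicate block. Tests were two-sided, and a gene passed at a Benjamini-Hochberg adjusted p under 0.05. The comparisons were HFD24 with ND, PTFC with HFD24, HFD16 with ND, HFD24 with HFD16 and PTFC with ND, and an F test over the 4 groups. Errors of log2 differences are standard errors (SE) from this fit. There were 35 gene lists of pathways and cell type markers with 673 entries, of which 557 had a probe, or 542 of 657 different genes. Lists with at least 5 measured genes, 34 of them, were tested with camera at a preset correlation of 0.01, with a Benjamini-Hochberg adjustment over the lists of a comparison, and again with an estimated correlation. The fry test, which asks whether the genes of a list move one way on balance and compares them with no other genes, was run as well. Counts of list members past the test are given with the adjustment over all genes and with the adjustment over the list alone. A comparison of a single value between 3 and 3 arrays used an exact two-sided permutation test, whose smallest p is 0.1.

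The rule for naming genes took, for HFD24 with ND and PTFC with HFD24, the 10 higher and 10 lower genes of largest difference among those that passed and whose 3 and 3 arrays did not overlap. For the other comparisons it took 5 and 5, and where fewer than 5 passed in a direction, the 5 of smallest unadjusted p in that direction, described as not past the test. It added up to 4 members of each list with the smallest p in that comparison, and Vegfc always. Symbols of predicted or unnamed transcripts were passed over for naming and counted. Genes named outside the rule are said to have been chosen after their values were seen. Of 112 named genes with another probe, counted per comparison, that probe gave the opposite direction in 32, and with an unadjusted p under 0.05 in 10, which are stated where such a gene is named.

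The groups, lists, naming rule, tests and other settings were chosen before the data were examined. The alternatives were median centring in place of quantile normalization, a pseudocount of 32, leaving out the dimmest 25% or the dimmest 50% of probes, all probes or the mean of a gene's probes, no trend, array weights, a replicate block, only the 6 arrays compared, a 2-fold minimum, and leaving out each array in turn. Added after seeing the data were the scale of the authors without further normalization, log2 of the scaling step as a covariate, list counts without the third ND array, the brighter 50% of genes, and the direction and size of each list and the share of the diet effect returned under other settings. Whether replicate numbers pair the samples was checked from the correlation of same-numbered arrays' deviations from their group means, which lay between -0.288 and 0.147. In HFD16 with ND all 3 pairs were above 0.1 (0.121, 0.147 and 0.105), smaller in size than the -0.288 at the other end. The labels tie the numbers to nothing shared, so whether arrays of HFD16 and ND are paired stays open. The blocked fit called 2766 genes there against 3462.

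The fit was tested on simulated data with the spread of these arrays, in which 67 of the 19084 genes were changed 1.5-fold, 67 were changed 2-fold and 66 were changed 4-fold. For HFD24 with ND it recovered 95.5% of genes changed 4-fold, 56.7% of those changed 2-fold and 8.96% of those changed 1.5-fold, with 5 false calls. For PTFC with HFD24 it recovered 98.5%, 67.2% and 8.96%, with 4 false calls. The simulated noise was normal and independent between genes and arrays. Genes on real arrays can vary together and far more of them passed there, so these rates may not carry over. Comparisons that share arrays share their chance values, so unchanged groups were simulated 100 times for each such pair. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.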

Results

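Gene expression was measured in the liver of male C57BL/6 mice on 12 arrays, 3 per group, in a study that asked how PTFC acts on fatty liver brought on by a high-fat diet, and its title names VEGF-C, the product of Vegfc, as a predicted target. ND mice ate a normal diet for 24 weeks, HFD16 and HFD24 mice the high-fat diet for 16 and 24 weeks, and PTFC mice the high-fat diet with the extract at 50 mg per kg per day for 18 weeks. Median intensity per array was 379, 376 and 300.3 for ND, 278, 330.1 and 287 for HFD16, 249, 336 and 338 for HFD24, and 406, 369 and 408 for PTFC. Arrays of one group correlated at a median r of 0.988 (0.981 to 0.993 over 12 pairs) and arrays of different groups at 0.981 (0.961 to 0.989 over 54 pairs), across genes, which are not independent replicates. On the first principal component, with 39.4% of the variance, the 6 arrays of the high-fat diet alone lay between 7.57 and 49.8, the ND arrays between -61.1 and -31.1 and the PTFC arrays between -28.3 and -9.69. The third ND array stood apart from the other ND arrays on the next components, at -34.2 on the third against 10.3 and 19.4.

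**Figure D1:**
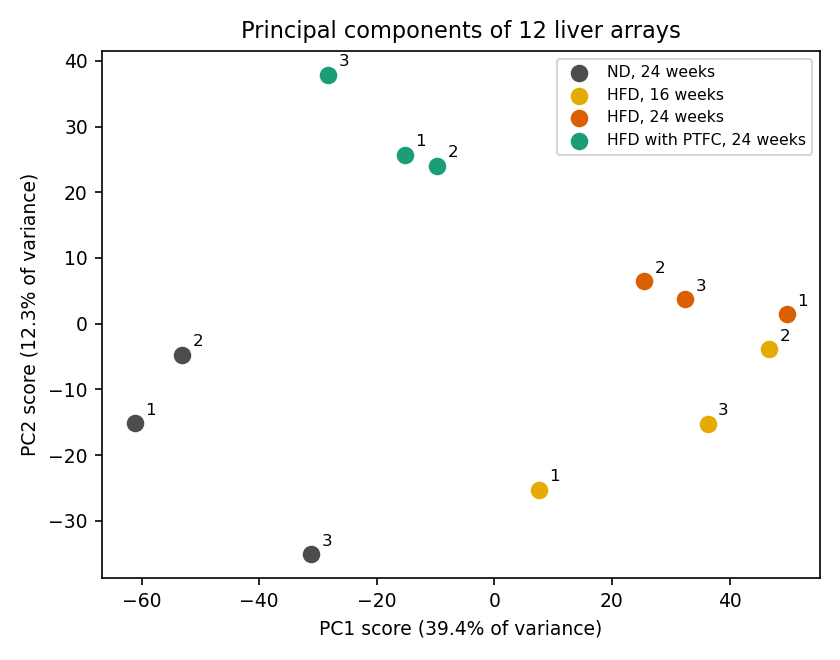
First (39.4% of the variance) and second (12.3%) principal components of normalized log2 intensity over 19084 genes, in arbitrary units, with 1 point per array and 1 colour per group. The 6 HFD16 and HFD24 arrays sit right of 0 on the first axis, all ND and PTFC arrays left of it, and the PTFC arrays lie highest on the second axis, between 24.0 and 37.9.

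The comparison of HFD24 with ND addressed the effect of the high-fat diet at 24 weeks. Timp1, which inhibits matrix metalloproteinases, was 76.5-fold higher in HFD24 (log2 6.26 ± 0.65, SE, n = 3 per group), and Lcn2, an acute phase protein that binds bacterial iron chelators, was 61.3-fold higher (log2 5.94 ± 0.61). Among chemokines, Ccl2, which draws monocytes, rose 27.8-fold (log2 4.80 ± 0.36), Cxcl9, which draws T cells, 27.2-fold (log2 4.76 ± 0.78), and Cxcl1, which draws neutrophils, 23.1-fold (log2 4.53 ± 0.30). Gpnmb, a glycoprotein of lipid-laden macrophages, rose 42.9-fold, and Cd74, the invariant chain of MHC class II, 20.8-fold. These folds depended on the probe. Another Gpnmb probe gave log2 1.19 against 5.42, another Cxcl9 probe 3.07, and other Cd74 probes 2.45 and 4.51 against 4.38. Of the sterol synthesis enzymes, Sqle, squalene epoxidase, was 6.78-fold lower (log2 -2.76 ± 0.22), and Idi1, isopentenyl diphosphate isomerase, 6.26-fold lower (log2 -2.65 ± 0.23). By limma with Benjamini-Hochberg adjustment, 3483 of 19084 genes passed, 1903 higher (54.6%) and 1580 lower. At least 2-fold differences numbered 1503, 1167 higher and 336 lower.

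Also among the 10 largest increases were Ubd, a ubiquitin-like protein induced by interferon (log2 5.06 ± 0.86), Cdk5r1, the activator of the kinase Cdk5 (log2 4.62 ± 0.59), and Slpi, a secreted protease inhibitor (log2 4.56 ± 0.52). The other large decreases were Dct, a melanin synthesis enzyme (log2 -3.52 ± 0.42), Cenpu, a centromere protein (log2 -3.20 ± 0.37), Ppp1r3g, which targets protein phosphatase 1 to glycogen (log2 -3.17 ± 0.65), Qser1 (log2 -2.90 ± 0.81), Cabyr (log2 -2.85 ± 0.49, while another probe of it gave 0.51), Fam222a (log2 -2.60 ± 0.29), Ptx4 (log2 -2.58 ± 0.38) and Gadd45g, a stress response gene (log2 -2.52 ± 0.61). The limma adjusted p of the 20 ran from 2.16e-05 for Cxcl1 to 0.0259 for Qser1. In 5 of the 20, Timp1 and Ccl2 among them, the group with the lower level lay in the dimmest 25% of signal, where the fold is least certain. Timp1 read 14.8 to 26.4 in deposited intensity on the ND arrays, whose 25th percentiles were 69.2 to 91.2. With a pseudocount of 32 the named genes of largest difference kept 77.6% to 99.7% of their log2 size. In 33.6% of all genes the 3 HFD24 arrays did not overlap the 3 ND arrays, against 10% by chance. Without the first ND array 1734 genes passed, without the second ND array 1902 and without the first HFD24 array 1990. Qser1 lost its call without the first ND array (limma adjusted p = 0.091), the second (0.0701), the first HFD24 array (0.117) or the third (0.0927), in a range of 0.000535 to 0.287 over all settings. The higher share was 54.6% after quantile normalization and 41.3% on the scale of the authors, where the median of all genes shifted by -0.23 (log2). With the scaling step as a covariate, which was largest in ND, 1086 genes passed, while the named genes of largest difference kept a median of 86.5% of their size.

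**Figure D2:**
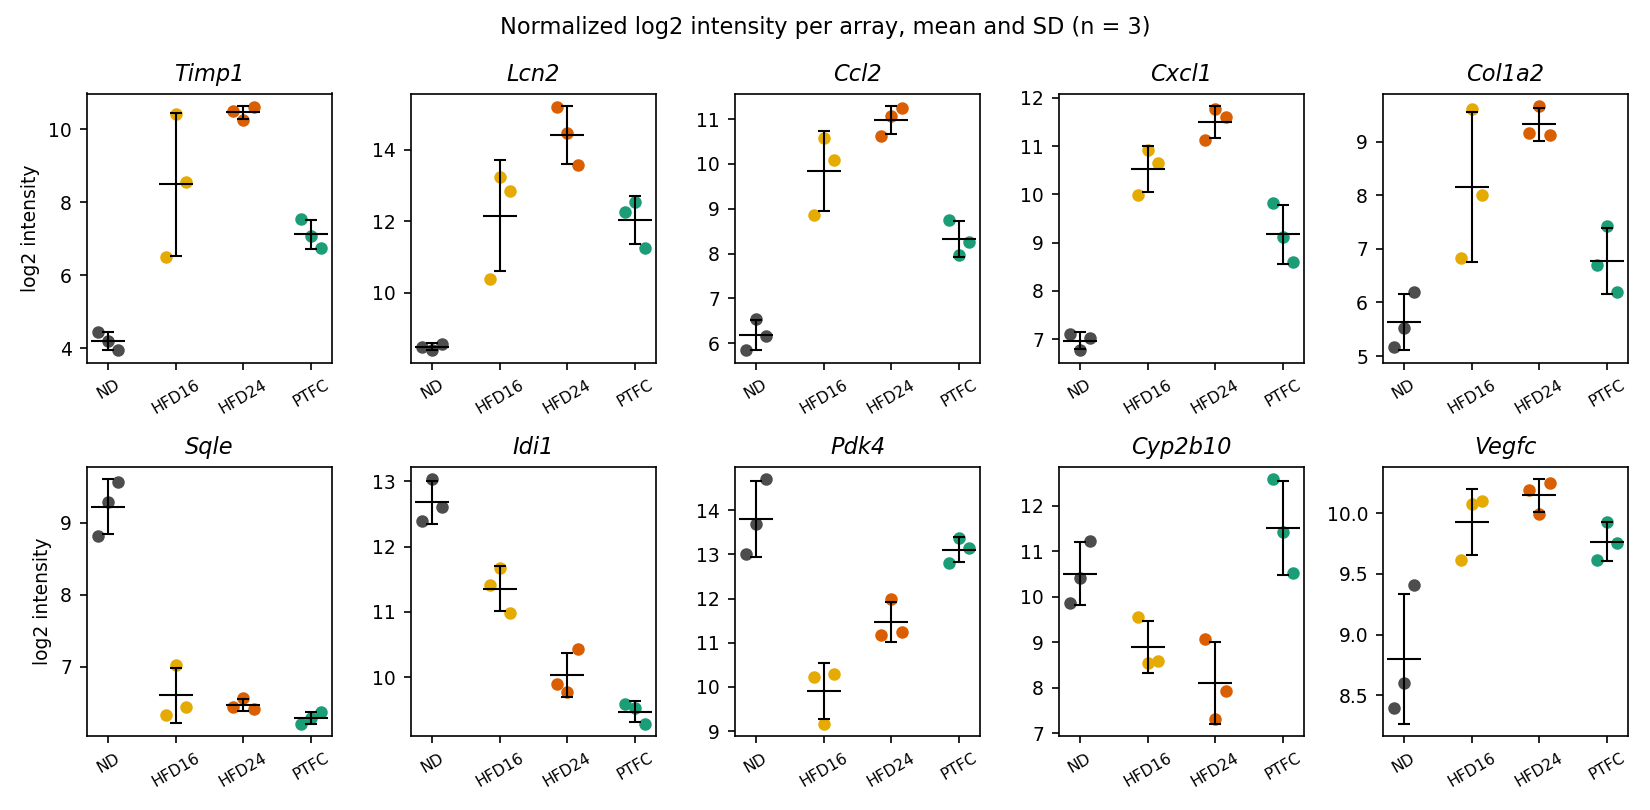
Normalized log2 intensity of 10 genes in each array (points) of the 4 groups, with the group mean and SD (bars, n = 3). Timp1 lies between 3.94 and 4.45 on the ND arrays, between 10.26 and 10.61 on the HFD24 arrays and between 6.76 and 7.54 on the PTFC arrays, while Idi1 lies between 12.39 and 13.03, between 9.78 and 10.42, and between 9.28 and 9.59.

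Immune and matrix lists rose together in HFD24 against ND. In the stellate cell and matrix list 20 of 25 measured members rose and 1 fell (21 and 1 adjusted over the list alone), with Sparc at 2.44 ± 0.22, Col3a1 at 3.31 ± 0.43 and Lrat, which stores retinol in stellate cells, at 2.24 ± 0.31 log2. The matrix list passed camera (adjusted p = 6.16e-14, and adjusted p = 0.167 with an estimated correlation). The member that fell was the collagen gene Col1a1 (log2 -0.91), named after its values were seen. Of the monocyte and lipid-associated macrophage markers 15 of 18 rose and 1 fell (the same adjusted over the list alone), including Cd63 (2.88, while another probe gave 0.24), Cx3cr1 (3.10), Cd68 (2.96) and Tyrobp (3.41). These macrophage markers passed camera (adjusted p = 4.46e-09, and adjusted p = 0.167 with an estimated correlation). The Kupffer cell list, markers of resident liver macrophages, had 10 of 12 members higher (11 adjusted over the list alone), with Folr2 at 1.60 and Cd5l at 2.42 (camera adjusted p = 6e-08, and adjusted p = 0.203 with an estimated correlation). Interferon response genes rose in 15 of 21 cases (17 adjusted over the list alone), with Isg15 at 2.07, Psmb9 at 2.72 and Ifi27l2a at 2.73 (camera adjusted p = 1.06e-10, and adjusted p = 0.203 with an estimated correlation). Cytokines, chemokines and adhesion molecules rose in 15 of 24 cases (15 higher and 1 lower adjusted over the list alone), with Ccl3 at 2.65 and the receptor Tlr2 at 2.81 (camera adjusted p = 2.74e-10, and adjusted p = 0.203 with an estimated correlation).

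Other cell types followed in part. Endothelial markers rose in 10 of 17 cases (11 adjusted over the list alone), with the lymphatic and sinusoidal marker Lyve1 at 3.03 ± 0.49 and Cdh5 at 1.25 (list median 0.72). As a list, endothelial markers passed camera (adjusted p = 2.02e-08, and adjusted p = 0.167 with an estimated correlation). T and NK cell markers rose in 5 of 15 cases (8 adjusted over the list alone), with Nkg7 at 2.30, Cd5 at 2.18 and Thy1 at 1.74. The camera adjusted p of that list was 3.36e-04, and adjusted p = 0.402 with an estimated correlation. Neutrophil markers rose in 7 of 13 cases and fell in 1 (8 and 2 adjusted over the list alone), with S100a9 at 2.73 and Csf3r at 1.93. Neutrophil markers passed camera (adjusted p = 0.00738, and adjusted p = 0.203 with an estimated correlation). Acute phase genes rose in 5 of 18 cases (8 adjusted over the list alone), with Steap4 at 2.03 and Hpx at 0.60. The acute phase list passed camera (adjusted p = 3.22e-04, and adjusted p = 0.345 with an estimated correlation). Of the hepatocyte markers 1 of 14 fell, the amino acid enzyme Tat at -0.87, and the other 13 did not pass, with Rbp4 at -0.22, Hnf4a at -0.27 and Apob at 0.58 (list median 0.03, mean -0.06 and test downward, camera adjusted p = 0.828). Tat lost its call without the third HFD24 array (limma adjusted p = 0.0624, in a range of 0.0111 to 0.0943 over all settings). Cholangiocyte markers fell in 3 of 10 cases, with the tight junction gene Cldn7 at -1.57 (camera adjusted p = 0.319).

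Lipid genes moved by pathway in HFD24 against ND. Cholesterol synthesis genes fell in 10 of 18 cases (11 adjusted over the list alone), with Hsd17b7 at -1.65 ± 0.20 and Msmo1 at -1.51 ± 0.19 beside Sqle and Idi1 (list median -0.77). This synthesis list passed camera (adjusted p = 5.07e-08, and adjusted p = 0.0692 with an estimated correlation). Fatty acid oxidation genes fell in 8 of 23 cases (12 adjusted over the list alone), with Pdk4, the kinase that shuts off pyruvate dehydrogenase, at -2.32 ± 0.40 and the acyl-CoA thioesterase Acot1 at -1.62 ± 0.26. Oxidation genes passed camera (adjusted p = 1e-04, and adjusted p = 0.132 with an estimated correlation). Sterol efflux genes rose in 6 of 10 cases (6 higher and 1 lower adjusted over the list alone), with the sterol transporters Abcg1 at 2.61 ± 0.23, Abcg5 at 0.98 and Abcg8 at 0.87. The efflux list passed camera (adjusted p = 9.37e-04, and adjusted p = 0.0926 with an estimated correlation). Lipid droplet and uptake genes went both ways, 5 of 21 higher and 6 lower (6 and 7 adjusted over the list alone), with the droplet protein Cidea higher by 3.71 ± 0.69, the fatty acid binding protein Fabp2 at 1.13 ± 0.15, and the fatty acid transporter Cd36 at -1.09 ± 0.19, although another Cd36 probe gave 0.67 (camera adjusted p = 0.489). Fatty acid synthesis genes had 1 of 19 members higher, the regulator Srebf1 at 1.64 ± 0.28, and 3 lower, among them the pyruvate kinase Pklr at -1.02 (camera adjusted p = 0.665). In bile acid synthesis and transport 2 of 21 members rose, Nr0b2 and the exporter Abcc4 at 1.27, and 2 fell, the hydroxylase Cyp7b1 at -1.01 and the transporter Slco1a4 at -1.68 (camera adjusted p = 0.356). Nr0b2 at 1.64 lost its call without the second ND array (limma adjusted p = 0.112), the third ND array (0.0775), the first HFD24 array (0.0975) or the third (0.083), in a range of 0.00652 to 0.112 over all settings.

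Gluconeogenesis and insulin signalling genes fell in 5 of 15 cases (8 lower and 1 higher adjusted over the list alone), with the insulin receptor substrate Irs2 at -1.96, the coactivator Ppargc1a at -1.40, Igfbp1 at -1.80 and the glucose-releasing enzyme G6pc at -1.05. As a group these genes passed camera (adjusted p = 0.0102, and adjusted p = 0.376 with an estimated correlation). That list's camera adjusted p was 0.0548 without the third ND array, from a range of 8.67e-04 to 0.0548 with 1 array left out, and 0.105 under median centring. Pancreas genes, a check of dissection, fell in 2 of 10 cases (4 adjusted over the list alone), with Cpb1 at -1.08. The pancreas list passed camera (adjusted p = 0.0231, and adjusted p = 0.345 with an estimated correlation) and lost the call without the third ND array (0.0596) or the first HFD24 array (0.0931, from 0.0073 up with 1 array left out). B cell markers rose in 5 of 12 cases and fell in 2 (6 and 3 adjusted over the list alone), and those that rose most were the MHC class II genes H2-Aa (3.66 ± 0.57), H2-Ab1 (3.61) and Cd74, which macrophages and dendritic cells also express. This B cell list passed camera (adjusted p = 0.0369, and adjusted p = 0.421 with an estimated correlation). The B cell call was lost without the third ND array (0.119) or the first HFD24 array (0.0592), from a lowest value of 0.0255 with 1 array left out. Antioxidant response genes rose in 4 of 14 cases (4 adjusted over the list alone), with the heme-degrading Hmox1 at 1.93 and Nqo1 at 0.79. Antioxidant genes passed camera (adjusted p = 0.0369, and adjusted p = 0.421 with an estimated correlation) and lost the call without the first ND array (0.0736), the second (0.0525) or the third HFD24 array (0.359), from a lowest value of 0.0039. The skeletal muscle, adipocyte, oxidative phosphorylation and cytosolic ribosome lists did not pass (camera adjusted p = 0.978, 0.296, 0.548 and 0.489), and the muscle list had a median of -0.26 and a mean of -0.07 while its test pointed up. Of 108 list members called in HFD24 against ND, 4 to 17 lost their call with 1 array left out.

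Vegfc, a growth factor of lymphatic vessels, was 2.55-fold higher in HFD24 than in ND (10.15 ± 0.13 against 8.80 ± 0.53 log2 intensity, SD, n = 3; log2 1.35 ± 0.24, SE, limma adjusted p = 0.00249). In HFD16 it was 2.19-fold higher than in ND (log2 1.13 ± 0.24, limma adjusted p = 0.00843). PTFC lay at 9.76 ± 0.16, 0.38 log2 units under HFD24 with no call (log2 -0.38 ± 0.24, limma adjusted p = 0.35), and 0.97 above ND (limma adjusted p = 0.0535). The 3 arrays of each group did not overlap in these 4 comparisons, which gave an exact permutation p of 0.1, the smallest that 3 against 3 can give. HFD24 and HFD16 overlapped (log2 0.22, exact permutation p = 0.3). Over 16 other settings, single arrays left out included, the HFD24 difference was 1.08 to 1.65 and passed in all but the fit with the scaling step as a covariate (limma adjusted p = 0.0502, from a range of 0.000151 to 0.0502). The PTFC difference from HFD24 was -0.57 to -0.20 and passed in none (limma adjusted p 0.151 to 0.577). PTFC against ND passed in 5 of the 16 (limma adjusted p 0.00158 to 0.377), and HFD16 against ND in all but the fit with the scaling step as a covariate (0.232, from 3.02e-05 up). Among VEGF and angiopoietin genes 3 of 14 rose and 2 fell in HFD24 against ND, the same counts adjusted over the list alone (camera adjusted p = 0.561). In PTFC against HFD24 Vegfb at -0.63 and the coreceptor Nrp1 at -0.42 were the members with the smallest p and did not pass (limma adjusted p = 0.0956 and 0.0971). Another Nrp1 probe gave -0.80 there (limma unadjusted p = 0.00238).

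In PTFC against HFD24, which addressed the effect of the extract on the same diet, inflammatory and matrix genes were lower. Ccl2 was 6.3-fold lower with PTFC (log2 -2.66 ± 0.36, SE, n = 3 per group), Cxcl1 was lower by log2 -2.32 ± 0.30, Timp1 was 10.1-fold lower (log2 -3.33 ± 0.65) and the collagen gene Col1a2 5.83-fold lower (log2 -2.54 ± 0.54). Cyp2b10, a cytochrome P450 induced through the receptor CAR, was 10.6-fold higher (log2 3.40 ± 0.53), Zbtb16, a transcription factor, 5.34-fold higher (log2 2.42 ± 0.45) and Lpin1, a phosphatidate phosphatase and coactivator, 3.23-fold higher (log2 1.69 ± 0.26). By limma with Benjamini-Hochberg adjustment 1145 of 19084 genes passed, 564 higher (49.3%) and 581 lower. Of these 473 differed at least 2-fold, 151 higher and 322 lower. Non-overlapping arrays were found in 31.1% of genes, against 10% by chance. Further decreases were those of Ubd (log2 -3.56 ± 0.86), Htra4 (-2.76 ± 0.61), S100a4, a calcium-binding protein of fibroblasts and macrophages (-2.72 ± 0.49), Slpi (-2.51 ± 0.52), Lcn2 (-2.39 ± 0.61), Procr, the protein C receptor (-2.39 ± 0.53), and AA467197 (-2.37 ± 0.53). Further increases were those of Cenpf, a kinetochore protein (2.33 ± 0.35), Mageb4 (2.16 ± 0.46), Ccne2, cyclin E2 (1.84 ± 0.20, while a dimmer probe gave -0.71), Mfsd2a, a lysolipid transporter (1.80 ± 0.40), the odorant receptor gene Olfr1247 (1.71 ± 0.41) and Igfbp1 (1.71 ± 0.36). Il3 is given by array in the closing observations. The limma adjusted p of these 20 genes ran from 0.0033 for Ccne2 to 0.0406 for Lcn2, and in 6 of the 20 the lower group lay in the dimmest 25% of signal.

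Most of these calls were lost when some single array was left out. Without the third PTFC array 11 genes passed and 18 of the 20 named genes lost their call, and without the first HFD24 array 39 passed and 17 lost it. Their differences kept a median of 94.8% and 95.8% of their size in these fits, against 107% without the first PTFC array. The sizes thus changed less than the calls. These 20 genes were chosen on the same arrays for large differences without overlap, so a kept size is partly built in and does not settle how far the differences rest on those arrays. The counts were 233 without the second HFD24 array, 442 without the third, 468 without the first PTFC array and 354 without the second, with 9, 6, 5 and 10 of the 20 losing their call. Of 54 list members called here, 48, 34 and 25 lost their call without the first, the second and the third HFD24 array and 22, 32 and 51 without the first, the second and the third PTFC array. Cyp2b10 and Cxcl1 passed with each array left out (limma adjusted p up to 0.0446 and 0.0409). The higher share was 49.3% after quantile normalization, 37.3% under median centring and 90.5% on the scale of the authors, where the median of all genes shifted by 0.24 (log2).

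Several lists that had risen with the diet fell with PTFC. Cytokines, chemokines and adhesion molecules fell in 9 of 24 cases (16 adjusted over the list alone), with Ccl3 at -1.64 ± 0.29 and Tlr2 at -2.03 ± 0.37 beside Ccl2 and Cxcl1 (list median -1.06). Interferon response genes fell in 7 of 21 cases (18 adjusted over the list alone), with the peptide transporter Tap1 at -1.51 ± 0.33, Irf7 at -1.36 and Isg15 at -1.36 ± 0.30 (list median -0.97). Both had a camera adjusted p = 4.16e-09, and adjusted p = 0.378 with an estimated correlation. Matrix genes fell in 6 of 25 cases (8 adjusted over the list alone), with the crosslinking enzyme Loxl2 at -1.41 ± 0.26, the receptor Pdgfrb at -1.50 ± 0.28 and Col3a1 at -2.14 ± 0.43. The matrix list passed downward in camera (adjusted p = 2.25e-05, and adjusted p = 0.464 with an estimated correlation). Monocyte and lipid-associated macrophage markers fell in 2 of 18 cases, Cx3cr1 at -1.75 ± 0.44 and Itgax at -1.31 (8 lower and 1 higher adjusted over the list alone), with a list median of -0.94. These markers passed camera (adjusted p = 1.06e-04, and adjusted p = 0.389 with an estimated correlation). T and NK cell markers fell in 2 of 15 cases, Cd5 at -1.87 and Thy1 at -1.37 (4 adjusted over the list alone). The T and NK cell list passed camera (adjusted p = 0.00417, and adjusted p = 0.553 with an estimated correlation). Of the Kupffer cell markers 1 of 12 fell, the iron exporter Slc40a1 at -0.86 (2 adjusted over the list alone), while Timd4 at -1.33 and Marco at -1.84 did not pass (camera adjusted p = 0.00577, and adjusted p = 0.572 with an estimated correlation, and 0.0581 at the preset without the second HFD24 array, from 7.24e-04 up with 1 array left out). Acute phase genes fell in 2 of 18 cases, Lcn2 and Steap4 at -1.29 (2 adjusted over the list alone; camera adjusted p = 0.00233, adjusted p = 0.464 with an estimated correlation, and 0.0553 at the preset without the third PTFC array, from 1.04e-05 up).

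Fatty acid oxidation genes rose with PTFC in 7 of 23 cases (12 adjusted over the list alone), with Acot1 at 1.24 ± 0.26, Pdk4 at 1.63 ± 0.40 and Hadha, a subunit of the mitochondrial trifunctional protein, at 1.14 ± 0.28 (list median 0.41). The oxidation list passed camera (adjusted p = 1.86e-06, and adjusted p = 0.129 with an estimated correlation). Under median centring 1 of the 23 rose and the median was 0.17, and on the scale of the authors 10 rose and the median was 0.54. Lipid droplet and uptake genes rose in 4 of 21 cases and fell in 1 (6 and 1 adjusted over the list alone), with the droplet coat protein Plin5 at 1.04 ± 0.21, Cd36 at 1.00 ± 0.19, and the triglyceride lipase Pnpla2 at 0.80 ± 0.17, while the lipase Lipe fell (-1.02). Droplet genes passed camera (adjusted p = 0.0173, and adjusted p = 0.378 with an estimated correlation). That call was lost without the second HFD24 array (0.0744), without the third (0.0638; lowest with 1 array left out 4.99e-04), under median centring (0.134) and on the scale of the authors (0.0852). Among cholesterol synthesis genes 1 of 18 fell, the decarboxylase Mvd at -1.28 ± 0.22, and 1 rose, Hsd17b7 at 1.08 ± 0.20 (the same adjusted over the list alone; list median -0.36). The sterol list passed camera (adjusted p = 0.0169, and adjusted p = 0.378 with an estimated correlation). This call was lost without the third HFD24 array (0.111) or the second PTFC array (0.0625; lowest 0.01), and the median was -0.04 on the scale of the authors. Of the female-biased liver genes 1 of 11 rose, the steroid hydroxylase Cyp17a1 at 1.36 (1 adjusted over the list alone). Female-biased genes passed camera (adjusted p = 0.0169, and adjusted p = 0.378 with an estimated correlation). Of the neutrophil markers 1 of 13 fell, S100a9 at -1.73 (7 lower and 1 higher adjusted over the list alone). As a list, neutrophil markers passed camera (adjusted p = 0.0273, and adjusted p = 0.378 with an estimated correlation). The neutrophil call was lost without the first HFD24 array (0.1), without the first PTFC array (0.104; lowest 0.011), under median centring (0.14) and on the scale of the authors (0.0808). The other 22 lists did not pass (camera adjusted p 0.0843 to 0.872), including hepatocyte markers, with Tat at 0.70 and Cps1 at 0.65, and endothelial markers, with Rspo3 at -0.74. Of these, sterol efflux genes passed downward under median centring and on the scale of the authors (camera adjusted p = 0.00726 and 0.00711, against 0.0843). Antioxidant genes did so too (camera adjusted p = 0.0333 and 0.0301, against 0.144, and 0.0158 without the first HFD24 array). Endoplasmic reticulum stress genes passed downward under median centring (camera adjusted p = 0.0471, against 0.379). Without the second HFD24 array gluconeogenesis and pancreas genes passed upward (camera adjusted p = 0.00909 and 0.0408), and pancreas genes also without the third (0.0485).

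**Figure D3:**
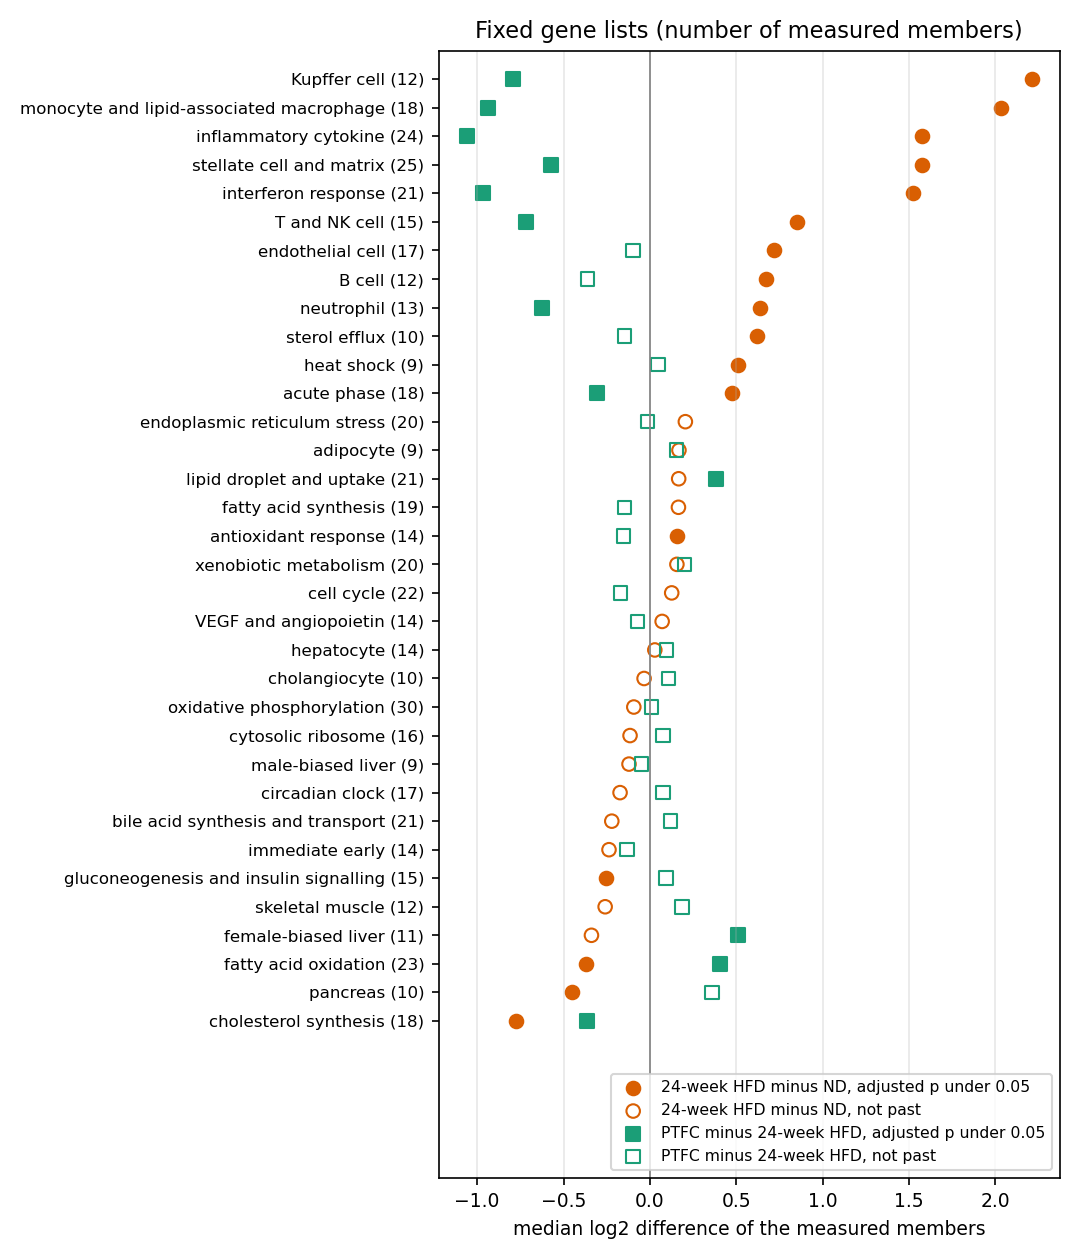
Median log2 difference of each of 34 gene lists (horizontal axis, log2 units) in HFD24 against ND (circles) and PTFC against HFD24 (squares), with filled symbols for lists past camera at an adjusted p under 0.05. The Kupffer cell and monocyte lists have the highest circles, at 2.21 and 2.03, and cytokine, interferon and monocyte lists the lowest squares, at -1.06, -0.97 and -0.94, while the cholesterol synthesis list is below 0 in both, at -0.77 and -0.36.

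Genes that responded to the diet at 16 weeks were followed into PTFC against HFD24, which shares no array with HFD16 against ND. The 1914 genes higher at 16 weeks had a median log2 difference of -0.53 with PTFC, and 91.5% of them were below 0, 345 past the test. The 1548 genes lower at 16 weeks had a median of 0.41, and 86.6% were above 0, 259 past the test, while 1 fell further past the test. Those medians were 53.2% and 67.7% of the size of the same genes' medians in HFD24 against ND. Such shares use the HFD24 arrays on both sides, and the ND arrays on which the sets were chosen, so shared chance values can shift them. With the sets called anew the shares were 63.6% and 71.2% under median centring and 31.9% and 96.0% on the scale of the authors. Both sets passed camera (p = 1.06e-41 and 2.3e-28, and p = 0.00912 and 0.015 with an estimated correlation) and fry (p = 0.00139 and 0.000819). On the scale of the authors, where all genes shifted by 0.24, the medians were -0.35 and 0.69. Across all 19084 genes, PTFC minus HFD24 correlated with HFD24 minus ND at r = -0.739 (Spearman -0.710), where unchanged groups sharing the HFD24 arrays gave a mean r of -0.510 (range -0.924 to 0.028). The covariance was -0.230 against a simulated -0.0468, a difference of -0.183. Of the genes higher in HFD24 than in ND, 427 fell with PTFC and of those lower 442 rose, where independent lists would share 57.9 and 46.7. Part of that excess may come from the shared HFD24 arrays, which 3 arrays are too few to split.

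**Figure D4:**
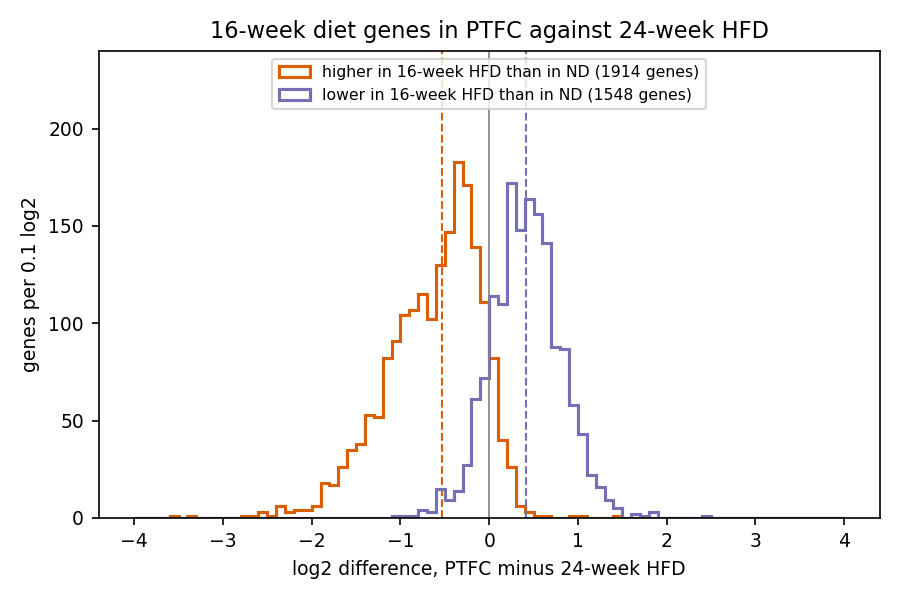
Number of genes (vertical axis) by log2 difference of PTFC minus HFD24 (horizontal axis), for the 1914 genes higher and the 1548 genes lower in HFD16 than in ND, with dashed lines at the medians. The higher set centres on -0.53 and the lower set on 0.41.

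HFD16 against ND addressed the diet at 16 weeks, with age, and possibly collection day, differing too. Cxcl9 was 33.2-fold higher (log2 5.06 ± 0.78, SE, n = 3 per group), Timp1 19.5-fold higher (log2 4.29 ± 0.65) and Cyp26a1, which breaks down retinoic acid, 14.0-fold higher (log2 3.80 ± 0.53). Another Cxcl9 probe gave log2 3.20. Timp1 ranged from 6.50 to 10.41 log2 intensity over the HFD16 arrays, so its fold depends on which arrays are used. Pdk4 was lower by log2 -3.90 ± 0.40, and the sterol enzyme Sqle was lower by log2 -2.63 ± 0.22. The Wnt agonist Rspo1 (3.67 ± 0.55) and the dendritic cell receptor Xcr1 (3.85 ± 1.13) rose as well, and Cenpu (-3.62), Ptx4 (-3.61), Ppp1r3g (-3.58) and Dct (-3.34) fell. By limma with Benjamini-Hochberg adjustment 3462 genes passed, 1914 higher (55.3%) and 1548 lower, with 1003 and 385 at least 2-fold. Of the 3462, 2106 also passed in the same direction at 24 weeks and 1 in the opposite one. Of the 2106, 1356 were higher and 750 lower, where independent lists would share 190.9 and 128.2. Non-overlapping arrays were found in 35.8% of genes, against 10% by chance. The 2 diet comparisons share the ND arrays and correlated at r = 0.854, where unchanged groups gave a mean of 0.466 and a range of -0.699 to 0.890 that holds it. The covariance was 0.336, against a simulated mean of 0.0429 (range -0.0278 to 0.1), and part of it may come from those shared arrays. The count was 1339 without the first ND array, 1908 without the second, 1939 without the second HFD16 array and 1588 without the third. Xcr1 lost its call without any of the 3 ND arrays (limma adjusted p = 0.0962, 0.0821 and 0.0534, in a range of 0.00238 to 0.153 over all settings). On the scale of the authors 34.4% of the calls were higher, and with the scaling step as a covariate 219 genes passed, with called list members at a median of 77.1% of their size.

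At 16 weeks interferon response genes rose in 15 of 21 cases (18 adjusted over the list alone), with the GTPase Gbp2 at 3.33, Psmb9 at 2.89 and Mx1 at 2.43 (camera adjusted p = 9.29e-11, and adjusted p = 0.322 with an estimated correlation). Matrix genes rose in 19 of 25 cases (20 adjusted over the list alone), with Sparc at 2.00 and Col3a1 at 2.58 (camera adjusted p = 4.28e-10, and adjusted p = 0.322 with an estimated correlation). Kupffer cell markers rose in 7 of 12 cases (10 adjusted over the list alone; camera adjusted p = 1.82e-05, and adjusted p = 0.322 with an estimated correlation). Monocyte markers rose in 9 of 18 (13 higher and 1 lower adjusted over the list alone; camera adjusted p = 9.3e-05, and adjusted p = 0.322 with an estimated correlation). Cytokines rose in 12 of 24 (14 and 1; camera adjusted p = 4.46e-05, and adjusted p = 0.322 with an estimated correlation). Endothelial markers rose in 7 of 17 (11; camera adjusted p = 5.34e-05, and adjusted p = 0.322 with an estimated correlation). T and NK cell markers rose in 6 of 15 (9; camera adjusted p = 9.49e-05, and adjusted p = 0.322 with an estimated correlation). The first HFD16 array lay nearest to ND, with list means of 8.58 for cytokines (10.21 and 9.52 on the other HFD16 arrays, 8.02 to 8.24 in ND), 7.67 for T and NK cells (9.28 and 8.58, and 7.31 to 7.51 in ND) and 10.92 for interferon (12.35 and 12.24, and 10.11 to 10.18 in ND). Timp1 stood there at 6.50, against 10.41 and 8.56. The third HFD16 array stood apart in markers of other tissues, with a skeletal muscle mean of 9.08 and the highest adipocyte mean, 10.68. Muscle did not pass with all arrays (camera adjusted p = 0.0727) and passed upward without the first HFD16 array (0.0098) or the second (0.0124). Fatty acid oxidation genes fell in 12 of 23 cases and rose in 1 (13 and 1 adjusted over the list alone), with the peroxisomal Pex11a at -1.22 ± 0.10, Acot1 at -2.24 and Angptl4 at -1.05. Oxidation genes passed downward in camera (adjusted p = 1.86e-08, and adjusted p = 0.0564 with an estimated correlation). Cholesterol synthesis genes fell in 9 of 18 cases (10 adjusted over the list alone), with Cyp51 at -1.56 and Msmo1 at -1.59. Sterol synthesis genes passed downward in camera (adjusted p = 9.08e-06, and adjusted p = 0.0881 with an estimated correlation). Sterol efflux genes rose in 4 of 10 cases and fell in 1 (5 and 1 adjusted over the list alone), with Abcg1 at 2.08 and Abca1 at 0.69. Efflux genes passed upward in camera (adjusted p = 0.00772, and adjusted p = 0.153 with an estimated correlation). Gluconeogenesis genes fell in 5 of 15 cases (5 lower and 1 higher adjusted over the list alone; camera adjusted p = 0.00191, adjusted p = 0.322 with an estimated correlation, and 0.0857 under median centring). Acute phase genes rose in 4 of 18 (6 higher and 1 lower; camera adjusted p = 0.0138) and B cell markers rose in 5 of 12 (6 and 1; camera adjusted p = 0.0138, and 0.0533 without the third ND array, from 3.37e-04 up), with adjusted p = 0.416 and 0.322 with an estimated correlation. Pancreas genes fell in 2 of 10 cases (2 adjusted over the list alone). Pancreas genes passed camera (adjusted p = 0.0365, and adjusted p = 0.322 with an estimated correlation) and lost the call without the first ND array (0.0629), the third (0.0643) or the third HFD16 array (0.0522), from a lowest value of 0.019. Of the lipid droplet genes 9 of 21 fell and 3 rose (11 and 4 adjusted over the list alone), with the lipase inhibitor G0s2 at -2.19 and Plin5 at -1.35, and the list did not pass (camera adjusted p = 0.0656), except without the first ND array (0.0353) or the first HFD16 array (0.0459, in a range up to 0.12). Of 110 list members called at 16 weeks, 30, 22 and 8 lost their call without the first, the second and the third ND array and 9, 27 and 27 without the first, the second and the third HFD16 array.

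Between 16 and 24 weeks of the diet 7 of 19084 genes passed (limma, Benjamini-Hochberg), against 1866 at an unadjusted p under 0.05, and the 2 groups also differed in age and possibly in collection day. Cidec, a lipid droplet protein of fat storage, was 3.84-fold higher at 24 weeks (log2 1.94 ± 0.23, SE, n = 3 per group), Ly6d was higher by 2.14 ± 0.29 and Pex11a by 0.73 ± 0.10. Clec2h (-2.07 ± 0.24), Adgrf1 (-1.83 ± 0.19), Olfr214 (-1.44 ± 0.20) and the Wnt receptor Fzd2 (-1.17 ± 0.17, while another probe gave 0.39) were lower. The droplet gene Cidea at 3.98 ± 0.69 and the apolipoprotein gene Apoa4 at 1.51 did not pass (limma adjusted p = 0.0884 and 0.0796). With 1 array left out 3 to 10 genes passed, 3 in the fit without the first HFD16 array and 4 in that without the first HFD24 array. Cidec, Adgrf1 and Clec2h passed in all 6 of those fits, while Pex11a, Ly6d, Olfr214 and Fzd2 passed in neither of the fits without the first HFD16 or the first HFD24 array (limma adjusted p 0.0634 to 0.0911) and failed in 3, 2, 2 and 4 of the others, up to 0.143 for Fzd2. Under median centring Cidec, Ly6d and Pex11a did not pass (limma adjusted p = 0.0682, 0.0682 and 0.405, the highest of their settings for Cidec and Pex11a). On the scale of the authors Adgrf1, Clec2h, Fzd2 and Pex11a did not pass (limma adjusted p = 0.0714, 0.0714, 0.0836 and 0.0998), and the lowest values over the settings were 0.000473, 0.000698, 0.00785 and 0.00785. Of the calls 42.9% were higher, against 66.7% on the scale of the authors.

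At the preset correlation 9 lists passed camera between 16 and 24 weeks, 8 of them upward. Cytokines had a median of 0.68, with 12 of 24 members higher and 1 lower at an unadjusted p under 0.05 and all short of the adjusted limma test (8 and 1 adjusted over the list alone). The cytokine list passed camera (adjusted p = 6.52e-07, and adjusted p = 0.523 with an estimated correlation). Its median was 1.09 without the second HFD16 array and 0.31 without the first, where its mean was -0.04 (camera adjusted p = 0.0246, from 1.38e-14 up with 1 array left out). Without the first HFD16 array interferon response genes (median -0.53) and T and NK cell markers (-0.51) passed downward (camera adjusted p = 1.47e-05 and 2.6e-05), against 0.998 and 0.681 with all arrays. T and NK cell markers passed upward without the second HFD16 array (camera adjusted p = 0.0194). Lipid droplet genes had 1 of 21 members higher, Cidec (9 adjusted over the list alone; median 0.48, and 0.31 without the first HFD24 array), with camera adjusted p = 1.55e-05, adjusted p = 0.177 with an estimated correlation, and fry adjusted p = 0.0482, and this was the list fry called. Monocyte markers had a median of 0.55, with 6 of 18 higher at an unadjusted p under 0.05 (3 adjusted over the list alone). The monocyte list passed camera (adjusted p = 1.55e-05, and adjusted p = 0.523 with an estimated correlation), with a median of 0.16 without the first HFD16 array and 1.08 without the second. Immediate early genes had a median of 0.65, with 7 of 14 higher at an unadjusted p under 0.05 (2 adjusted over the list alone). The immediate early list passed camera (adjusted p = 6.85e-05, and adjusted p = 0.476 with an estimated correlation), with a median of 0.39 without the first HFD16 array. Fatty acid oxidation genes had 1 of 23 members higher, Pex11a (6 adjusted over the list alone). The oxidation list passed upward in camera (adjusted p = 1.05e-04, and adjusted p = 0.177 with an estimated correlation). Matrix (median 0.28), endothelial (0.22) and Kupffer cell markers (0.48) passed upward, with 6 of 25, 5 of 17 and 2 of 12 members higher at an unadjusted p under 0.05 (camera adjusted p = 0.00119, 0.0103 and 0.0219, and adjusted p = 0.593, 0.523 and 0.638 with an estimated correlation). Matrix lost its call without the first HFD16 array (0.352), endothelial without the third HFD16 array (0.114) or the first HFD24 array (0.0783), and Kupffer without the first HFD16 array (0.816), the first HFD24 array (0.0691) or the second (0.237), from lowest values of 1.45e-09, 9.75e-04 and 2.49e-04. The medians moved too, for matrix to 0.10 without the first HFD16 array and 0.54 without the second, for Kupffer cells to -0.03 and 1.01 in these fits and 0.72 without the third HFD24 array, and for endothelial cells to 0.07 without the third HFD16 array and 0.14 without the first HFD24 array. Skeletal muscle genes, a check of dissection, had a median of -1.03, which came from the third HFD16 array, at a list mean of 9.08 against 6.50 to 6.80 on the other 11 arrays. The median was -1.59 without the first HFD16 array and -0.05 without the third. The muscle list passed downward in camera (adjusted p = 0.00566, and adjusted p = 0.523 with an estimated correlation). For muscle the camera adjusted p was 0.9 without the third HFD16 array, from 1.47e-05 up. Without the second HFD16 array 14 lists passed.

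PTFC against ND compared diet plus extract with the normal diet. Sterol synthesis genes were far lower, Idi1 9.24-fold (log2 -3.21 ± 0.23, SE, n = 3 per group), Sqle 7.69-fold (log2 -2.94 ± 0.22) and the sterol carrier Stard4 by log2 -2.16 ± 0.25. Cidea was 20.4-fold higher (log2 4.35 ± 0.69), Cidec 3.94-fold (log2 1.98 ± 0.23), Gpnmb 13.8-fold and Lcn2 11.7-fold. Another Gpnmb probe gave log2 0.45, against 3.79 for the probe kept. Rgs16, a regulator of G protein signalling, was 13.5-fold higher (log2 3.76 ± 0.52). Dct (-4.09), Cenpu (-3.97) and Cabyr (-3.83, while another probe gave 0.09) were again lower. By limma with Benjamini-Hochberg adjustment 445 genes passed, 199 higher (44.7%) and 246 lower, with 266 at least 2-fold. Non-overlapping arrays were found in 22.1% of genes, against 10% by chance. The count was 64 without the first ND array, 258 without the second, and 212, 157 and 58 without the first, the second and the third PTFC array. Of the genes named here, Cidea lost its call without the third PTFC array (limma adjusted p = 0.0511, in a range of 0.00131 to 0.0705 over all settings), Lcn2 without the first ND array (0.0614, in 0.00158 to 0.156) and Gpnmb in each of the 6 such fits (0.0765 to 0.146), while Idi1, Sqle and Stard4 passed in all 6. With the scaling step as a covariate 54 genes passed, with called list members at a median of 90.1% of their size, and the higher share was 32.8% under median centring and 68.7% on the scale of the authors.

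Of the lists, cholesterol synthesis fell furthest in PTFC against ND, with 10 of 18 members lower (17 adjusted over the list alone; median -1.07), and it was the one that also passed with an estimated correlation. Sterol genes passed camera (adjusted p = 2.38e-21, and adjusted p = 0.00197 with an estimated correlation). Of 38 list members called in PTFC against ND, 26, 10 and 4 lost their call without the first, the second and the third ND array and 13, 17 and 25 without the first, the second and the third PTFC array. Matrix genes rose in 7 of 25 cases, Sparc at 1.74 among them, and fell in 1, Col1a1 at -1.10 (16 and 1 adjusted over the list alone). As a list, matrix genes passed camera (adjusted p = 8.85e-12, and adjusted p = 0.271 with an estimated correlation). Col1a1 lost its call without the first ND array (limma adjusted p = 0.112), the first PTFC array (0.0782) or the third (0.105), in a range of 0.0112 to 0.112 over all settings. Endothelial markers rose in 6 of 17 cases (10 adjusted over the list alone). The endothelial list passed camera (adjusted p = 1.11e-10, and adjusted p = 0.135 with an estimated correlation). Kupffer cell markers rose in 4 of 12 (8 adjusted over the list alone). As a list, Kupffer markers passed camera (adjusted p = 7.49e-06, and adjusted p = 0.373 with an estimated correlation). Monocyte markers rose in 4 of 18 (8 adjusted over the list alone). The monocyte list passed upward in camera (adjusted p = 7.49e-06, and adjusted p = 0.34 with an estimated correlation). Lipid droplet genes rose in 3 of 21 cases, Cidea, Cidec and Fabp2 at 1.02 (4 adjusted over the list alone). The droplet list passed camera (adjusted p = 2.53e-04, and adjusted p = 0.15 with an estimated correlation). Cytokines rose in 2 of 24, Cxcl1 at 2.21 and Ccl2 at 2.14 (4 adjusted over the list alone). The cytokine list passed upward in camera (adjusted p = 7.1e-04, and adjusted p = 0.478 with an estimated correlation). Sterol efflux genes rose in 1 of 10, Abcg1 at 1.65 (4 adjusted over the list alone). Sterol efflux passed camera (adjusted p = 0.00342, and adjusted p = 0.135 with an estimated correlation). Ccl2 lost its call without the first ND array (limma adjusted p = 0.068) or the third PTFC array (0.054), in a range of 0.00199 to 0.156 over all settings. Interferon response genes had a median of 0.46, with 6 of 21 higher at an unadjusted p under 0.05 and all short of the adjusted limma test (camera adjusted p = 0.00342, adjusted p = 0.537 with an estimated correlation, and 0.0541 without the first PTFC array, from 0.00102 up). Fatty acid oxidation genes had a median of -0.02 (camera adjusted p = 0.943). HFD24 minus ND and PTFC minus ND, which share the ND arrays, correlated at r = 0.669, inside the range of -0.755 to 0.911 that simulated unchanged groups gave. The covariance was 0.188, against a simulated -0.0234 to 0.109. They had 176 genes higher in both and 153 lower in both, where independent lists would share 19.8 and 20.4. Part of that excess may come from the shared ND arrays.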

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

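The test of a lower share of hepatocytes was chosen after the result was seen.

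By limma 7 genes differed between HFD24 and HFD16, groups that also differ in age, possibly in collection day, and have no ND group of 16 weeks beside them. Of the 7, 4 lost their call without the first HFD16 array or without the first HFD24 array. Cidec was higher at 24 weeks by 1.94 log2 units, Ly6d by 2.14 and Pex11a by 0.73, while Clec2h was lower by a log2 difference of -2.07, Adgrf1 by -1.83, Olfr214 by -1.44 and Fzd2 by -1.17. Cidec was 4711 to 5678 in deposited intensity on the first and the third HFD16 array and 3867 on the second, under the 6097, 7392 and 10130.0 of ND, against 14320.0 to 22590.0 on the HFD24 arrays and 29950.0 to 34160.0 on the PTFC arrays. Among the 4547 probes with no gene name here, which the comparisons of genes leave out, 491 passed limma in HFD24 against ND, 143 higher and 348 lower, and 229 in PTFC against HFD24, 183 higher and 46 lower.

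The first pattern weighed was that genes of the 16-week diet response moved the other way with PTFC. The gene sets came from the HFD16 and ND arrays, so chance values of shared HFD24 arrays were excluded by design rather than tested. The medians of the sets with PTFC lay 0.943 apart, a gap that 100 draws from residual arrays put at -0.372 to 0.446. Across all genes, HFD16 minus ND and PTFC minus HFD24 correlated at r = -0.618, where simulated unchanged groups gave r from -0.600 to 1. Their covariance was -0.181, against a simulated -0.0581 to 0.0616. Residuals of a real group balance out, so a draw that joins whole groups can give an r of 1 between comparisons that share no array. This and the wide range of r make such draws a rough measure of chance. A constant log2 shift of an array cancels in this gap, so the gap cannot test that kind of scaling. In the brighter 50% of genes the gap was 0.807 after quantile normalization, 0.911 under median centring and 0.773 at the least, on the scale of the authors. These values argue against dim probes as the whole cause. A response of the liver to the extract may lie behind the pattern, and that stays open as untested. The size of the move back depended on the scaling, at 53.2% and 67.7% of the 24-week medians for the higher and lower sets after quantile normalization, 63.6% and 71.2% under median centring, and 31.9% and 96.0% on the scale of the authors.

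The second pattern was the rise of immune and matrix lists in HFD24 against ND. A lower share of hepatocytes alone would raise the markers of all other liver cell types alike. Kupffer cell markers had a median of 2.21 and endothelial markers one of 0.72, a difference of 1.49 (12 and 17 members, permutation p = 0.00175). The permutation moved genes between the lists, and genes are not independent replicates, so its p measures no spread between samples. Between arrays, the list means rose by 1.93 (95% interval 0.89 to 2.97) for Kupffer cells and 0.91 (0.57 to 1.24) for endothelial cells. These intervals overlap, so the medians cannot decide on a lower share of hepatocytes. A lower share stays open as a cause of all or part of the rise. Brightness of the arrays was weighed by the scaling step, for the cytokine list alone. Its mean difference was 1.68 ± 0.34 (SE) without the step as a covariate and 1.21 ± 0.38 with it. The covariate lowered the count of genes from 3483 to 1086. Of 108 called list members 44 lost their call with it, and the median size was 86.2% of that without it. The steps of ND (1.23 to 1.46) and HFD24 (0.855 to 1.12) did not overlap. The adjustment thus rests on the spread within groups and cannot decide on brightness, which stays open. More immune cells in the liver, or higher expression in the cells already there, could each give such a rise, and bulk RNA leaves both open. Of the Kupffer cell list 0 members are held by another list and of the monocyte list 1.

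Other splits of the arrays were used to ask how often a regrouping gives as many calls. For each comparison of 3 with 3 arrays, 1 of the 10 splits, the real one, reached the real count, and 10 splits are too few for a share under 0.05. The real counts and the highest of the other splits were 3483 and 0 for HFD24 with ND, 1145 and 1 for PTFC with HFD24, 3462 and 1 for HFD16 with ND, 7 and 2 for HFD24 with HFD16, and 445 and 0 for PTFC with ND. For HFD16 with ND, where a pairing by number stays open, the highest other of the splits that part all same-numbered pairs was 0. In the F test over the 4 groups 1 of 100 splits, the real one with 4088 genes, reached that count and the highest other had 765. A share of 1 in 100 is the smallest these splits can give. It also treats the arrays as separate samples, which the labels do not state, so it cannot exclude chance between animals.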

How the results depend on the processing

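The scale of the authors, the scaling step as a covariate and the brighter 50% of genes were chosen after the data were seen. Comparisons are taken here in the order HFD24 with ND, PTFC with HFD24, HFD16 with ND, HFD24 with HFD16 and PTFC with ND, followed by the F test, and their counts of genes were 3483, 1145, 3462, 7, 445 and 4088. Every count given here as an alternative moved by more than 1.5 times unless said otherwise, none reversed, and the cause was not tested. With an estimated correlation camera called 0, 0, 0, 0 and 1 lists (6, 2, 3, 3 and 5 at an unadjusted p under 0.05), against 17, 12, 16, 9 and 13 at the preset. By fry 15, 8, 18, 1 and 6 lists passed, of which the first 3 counts moved by no more than 1.5 times. Of the lists past camera at the preset, 13, 7, 15, 1 and 6 also passed fry. Under median centring HFD24 with HFD16 had 4 genes and PTFC with ND 229. Without the dimmest 25%, where fewer genes were tested, HFD24 with HFD16 had 3. Without the dimmest 50% the first 4 comparisons had 1789, 309, 1897 and 11 and the F test 2074. Array weights gave 6044, 1747, 9116, 88, 2308 and 9681. A replicate block gave 337 for PTFC with HFD24 and 4 for HFD24 with HFD16, and lowered HFD24 with ND to 2830 and PTFC with ND to 318, by less than 1.5 times. Same-numbered arrays correlated between -0.288 and 0.147, and 3 of 15 pairs were over 0.1, all in HFD16 with ND. These values do not settle whether any arrays are paired. On the scale of the authors HFD24 with HFD16 had 3 genes. With the scaling step as a covariate the counts were 1086 for HFD24 with ND, 219 for HFD16 with ND, 11 for HFD24 with HFD16, 54 for PTFC with ND and 2038 for the F test. A 2-fold minimum, which can only lower a count, left 1503, 473 and 1388 in the first 3 comparisons and 266 in PTFC with ND. An unadjusted p with that minimum gave 1592 and 1538 for the diet comparisons with ND and 168 for HFD24 with HFD16. With only the 6 arrays compared, PTFC with HFD24 had 1745 and HFD24 with HFD16 had 0 by limma, against 1866 at an unadjusted p under 0.05 in the fit to 12 arrays.

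With single arrays left out, so with fewer samples, counts of genes moved over 1734 to 4939, 11 to 468, 1339 to 4516, 3 to 10, 58 to 616 and 2219 to 5186. The F test had 2219 without the first ND array, 2712 without the second and 2692 without the third HFD16 array. Counts of lists were 14 to 18, 11 to 12, 14 to 19, 8 to 14 and 10 to 15, of which 14 in HFD24 with HFD16, without the second HFD16 array, moved. Over left-out arrays, other scalings and a replicate block, 2 of 17, 5 of 22, 9 of 18, 12 of 25 and 5 of 21 lists short of camera in the fit to all arrays passed in at least 1 fit. The medians of the 16-week diet genes with PTFC stayed within -0.66 to -0.47 and 0.29 to 0.48, the correlation within -0.770 to -0.688 and Vegfc within 1.15 to 1.65. These 3 results stayed the same in every setting chosen beforehand. Of 354 called values of named genes 157 lost their call in some fit with an array left out, 213 in some other setting, and 0 reversed. Signal close to background limits the folds of dim genes.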

Other observations

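The test of a lower intake of the diet was chosen after the result was seen.

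Cyp2b10, a drug-metabolizing cytochrome P450 that is the usual readout of the receptor CAR, stood at deposited intensities of 974, 1402 and 2282 in ND, 427, 159 and 244 in HFD24, and 6104, 2842 and 1605 in PTFC. It fell with the diet at 24 weeks (log2 -2.40 ± 0.53, SE, n = 3 per group, limma adjusted p = 0.00855) and rose with PTFC. It was the one member of the xenobiotic metabolism list, 20 genes, that rose with PTFC, and Gstm3 fell (camera adjusted p = 0.545). The diet had raised Gstm3 (log2 2.23) and Cyp1b1 (1.47), and the list did not pass at 24 weeks (camera adjusted p = 0.3). At 16 weeks it was short of the test (camera adjusted p = 0.0548) and passed upward with a replicate block (0.0381), under median centring (0.0276), on the scale of the authors (0.0235), and without the first ND array (0.0312), the second (0.0336) or the second HFD16 array (0.0316), in a range up to 0.216 with 1 array left out. In PTFC against ND the list had a median of 0.28, with 3 of 20 members higher at an unadjusted p under 0.05 and all short of the adjusted limma test. The xenobiotic list passed camera (adjusted p = 0.0145, and adjusted p = 0.47 with an estimated correlation) and lost the call without the third ND array (0.135) or the first PTFC array (0.206), from 0.00119 up. Il3, a cytokine of blood cell growth, read 7.64, 337.3 and 462.4 on the 3 PTFC arrays and between -7.32 and 5.62 on the other 9, which is at background, so no fold is given. The droplet gene Cidea lay 3.71 above ND in HFD24 and 4.35 above it in PTFC, while its difference of 3.98 between HFD24 and HFD16 did not pass (limma adjusted p = 0.0884).

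Cell cycle genes rose in 9 of 22 cases and fell in 1 at 16 weeks against ND (10 and 2 adjusted over the list alone), with the replication helicase genes Mcm5 at 1.36 and Mcm2 at 1.01. As a list they passed camera (adjusted p = 0.0138, and adjusted p = 0.322 with an estimated correlation). At 24 weeks 7 rose and 2 fell (camera adjusted p = 0.0953), and the list passed upward without the second HFD24 array (0.0277, in a range up to 0.206). Among endoplasmic reticulum stress genes 7 of 20 rose at 16 weeks, the chaperone genes Sdf2l1 at 1.77, Calr at 1.05 and Pdia6 at 0.95 among them, and 3 fell, with Trib3 at -1.20 (10 and 3 adjusted over the list alone). The stress list passed camera (adjusted p = 0.0297, and adjusted p = 0.322 with an estimated correlation). That call was lost without the third ND array (0.0533) or the first HFD16 array (0.0681), from 0.017 up, and the list did not pass at 24 weeks (camera adjusted p = 0.258). The heat shock gene Hspa1a rose at 24 weeks (2.48) and the list passed against ND (3 of 9 higher and 1 lower adjusted over the list alone). The heat shock list passed camera (adjusted p = 0.0369, and adjusted p = 0.472 with an estimated correlation) and lost the call without the first ND array (0.131), the second HFD24 array (0.235) or the third (0.0517), from 0.00101 up. In PTFC against ND heat shock had a median of 0.55 (2 of 9 higher adjusted over the list alone). Heat shock genes passed upward in camera (adjusted p = 7.1e-04, and adjusted p = 0.373 with an estimated correlation). Immediate early genes, which respond to handling, went both ways at 24 weeks, 4 of 14 higher with Klf6 at 2.01 and 2 lower with Jun at -1.49 (median -0.24, mean 0.14 and test upward, camera adjusted p = 0.679). Male-biased liver genes fell in 3 of 9 cases in PTFC against ND, the peroxisomal coenzyme A diphosphatase gene Nudt7 at -1.47 among them (3 adjusted over the list alone). The male-biased list passed camera (adjusted p = 0.00214, and adjusted p = 0.34 with an estimated correlation). At 24 weeks of diet 3 of 9 fell, with the elongase Elovl3 at -1.57, and the list did not pass (camera adjusted p = 0.0552). It passed there without the first ND array (0.048), the second (0.0368), the second HFD24 array (0.0214) or the third (0.0458) and with a replicate block (0.0458), in a camera adjusted p range up to 0.258. Clock genes had 2 of 17 higher and 1 lower at 24 weeks, with Npas2 at 1.45 (camera adjusted p = 0.839). B cell markers in PTFC against ND had 3 of 12 members higher at an unadjusted p under 0.05 (3 adjusted over the list alone). The B cell list passed camera (adjusted p = 0.0397, and adjusted p = 0.478 with an estimated correlation) and lost the call without the first ND array (0.0705), the third (0.0976), the first PTFC array (0.0891) or the second (0.068), from 0.0143 up.

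The third pattern weighed was that the cholesterol synthesis list, low on the diet, was no higher with PTFC. The list mean was lower in HFD24 than in ND by a log2 difference of -1.02 ± 0.09 (SE), and PTFC minus HFD24 was -0.28, with a 95% interval of -0.49 to -0.0776. A lower intake of the diet, whose cholesterol represses these genes, might move the list back by about the smaller share of the 16-week diet genes. That would be a rise of 0.54, and the upper limit of -0.0776 lies under it. The expectation assumes that these genes return in step with the other diet genes, which was not tested, so the interval cannot decide on intake. Under median centring the interval was -0.72 to -0.14 against a rise of 0.58, and on the scale of the authors -0.31 to 0.18 against 0.35. An effect of the extract on sterol handling remains a candidate explanation that was not tested, and a lower intake stays open.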
